A study of Mus musculus with 2 samples.

How the data were processed

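Tumour-infiltrating myeloid cells of PyMT tumour-bearing mice were measured in 2 libraries, 1 from Dab2 floxed mice without Tie2-Cre (WT) and 1 from Dab2 floxed mice with Tie2-Cre (KO), each from tumours of 3 pooled mice. Tumours were digested for 1 h at 37 °C and cells were sorted before loading. Libraries were prepared with the 10x Genomics 3′ kit, version 2. The deposited values are raw UMI counts per gene and barcode, and they were checked to be whole numbers. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 3 and the mm10 build, with roles not given. The annotation release, the cell filter, the exons deleted and the sequencing dates are not given in the sources used here. Both tables list the same 15575 genes, and 15059 of these matched GENCODE M21 (GRCm38) by name, from which identifiers and coordinates were taken.

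Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 19 WT and 15 KO barcodes. Each barcode held at least 511 genes in WT and 502 in KO, so the gene minimum removed none. Scrublet, run per library through scanpy 1.11.5, called 5 WT and 10 KO barcodes, 0.290% of 5176, and so did not work as a doublet filter at these settings. Doublets are therefore in the data. After both filters, 2653 WT cells with 20403052 UMIs and 2474 KO cells with 17718033 UMIs were kept.

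Both libraries were clustered together without integration: 2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1 and seed 0, on values scaled to 10000 per cell and log-transformed. This gave 17 clusters. Each cluster took the class with the highest mean of marker CPM, each marker scaled to its highest cluster, among marker lists for 16 cell types. A marker under 100 CPM in every cluster scored 0, and a class needed at least 3 markers found in at least 10% of the cluster's cells. A cluster was to stay unnamed if its 10 leading genes, each seen in at least 25% of its cells, held more markers of another class than of its own; none did. The naming rule was settled after the clusters had been seen. The class names are therefore "-like" and rest on markers alone: macrophage-like (10 clusters), monocyte-like (clusters 5 and 13), cDC1-like, cDC2-like, mature dendritic, plasmacytoid dendritic and neutrophil-like (1 cluster each). Leading genes define the clusters and were not read as results.

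For each class, UMIs were summed per library and divided by the class total (CPM). Levels carry exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals, and log2 KO/WT ratios exact conditional binomial intervals, all at 95% and for counting error only. No test was made, since each group has 1 library and cells are not replicates. A fold against a count of 0 used a floor of 3 counts for the library. Dab2 shares were read after each cell with at least 2000 UMIs was thinned to 2000.

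The samples' groups, comparisons, 21 gene lists and marker lists were fixed before the data were examined. Of 591 symbols in the lists, 565 matched by name, 6 by synonym and 20 not at all. List members with at least 50 UMIs over both libraries were used, in lists with at least 5 of them. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and its counting interval came from 1000 redraws of the counts. Genes were named by a rule fixed at the same time: the 10 highest and 10 lowest ratios among genes with at least 100 UMIs in macrophage-like cells, without ribosomal, mitochondrial and immunoglobulin genes and predicted models, plus Dab2. In each other class with at least 50 cells per library, 5 each were named. For each list, up to 4 members were eligible, the pair with the highest CPM and the pair with the largest ratio. For genes that go with Dab2, the 10 highest and 10 lowest with at least 50 UMIs were taken from the thinned counts.

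The steps were tested on simulated data for macrophage-like KO against WT, over 9180 genes of which 200 were changed. Intervals covered the true ratio for 95.4% of unchanged genes, 95% of genes raised 1.5-fold and 93% of genes lowered 3-fold, with median log2 ratios of 0.60 and -1.58 for the changed genes. Of 200 unchanged lists of 20 genes, 3.5% lay outside the central 95% of random lists, and 100% of 20 lists shifted 1.25-fold lay above it. The simulation holds counting error alone and no variation between mice. Its lists were random genes drawn independently, so it does not show how often lists of genes that vary together reach an extreme percentile.

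Alternatives changed 1 choice at a time: the cell filter, doublet calls, resolution, clustering per library, scaling by the median ratio or by edgeR 4.0.16 TMM factors (R 4.3.3), cell weights, depth, UMI minima, the class, cycling cells and the Dab2 split. Sharing of 31-base words between transcripts was counted over their last 500 bases in the same annotation. Python 3.11.15 was used with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Left out were tests between genotypes, counts of changed genes and trajectories, which 1 library per group cannot bear.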

Results

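Tumour-infiltrating myeloid cells of MMTV-PyMT mice, which develop mammary tumours, were profiled by droplet single-cell RNA sequencing. One library came from mice with floxed Dab2 and no Cre (WT), and 1 from mice with floxed Dab2 and Tie2-Cre (KO), a driver active in endothelial and blood cells. Tumours of 3 mice were pooled for each library, and CD45-positive cells lacking CD3, CD19 and NK1.1 were sorted. The WT library held 2677 barcodes with 20512470 UMIs, a median of 6941 per barcode. The KO library held 2499 barcodes with 17884647 UMIs, a median of 6513 per barcode. After filtering, 2653 WT and 2474 KO cells remained. With 1 library per genotype no difference below has a replicate check, and mouse, sort, loading and sequencing differences cannot be separated from genotype. All intervals are 95% intervals and cover counting error only, unless another spread is named.

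The first question was how much Dab2 transcript remained after deletion, and in which myeloid cells Dab2 was found. Dab2 encodes an endocytic adaptor that links cargo such as lipoprotein receptors and integrins to clathrin (ENSMUSG00000022150.16, chromosome 15, 6299788 to 6440712, GRCm38). Over all kept cells it was lower in the KO library, at 84.6 CPM (80.4 to 89.0, 1499 UMIs; CPM are UMIs scaled to a common total) against 182 in WT (176 to 187, 3704 UMIs). The log2 KO/WT ratio was -1.10 (-1.19 to -1.01). In WT, Dab2 was highest in macrophage-like cells, at 214 CPM (206 to 222), followed by cDC2-like cells (conventional type 2 dendritic cells) at 171 (154 to 189). Monocyte-like cells had 105 CPM (94.3 to 117). Levels were low in cDC1-like cells (8 UMIs) and neutrophil-like cells (12.7 CPM, 4 UMIs), and mature dendritic and plasmacytoid dendritic cells had no Dab2 UMI in either library.

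In KO macrophage-like cells Dab2 stood at 98.6 CPM (93.5 to 104), a log2 ratio of -1.12 (-1.21 to -1.02). The difference was unequal between macrophage-like clusters: Dab2 had 253 CPM in WT and 89.9 in KO in cluster 11, 188 and 153 in cluster 1, and 274 and 280.5 (186 to 405) in cluster 12, which held 15 KO cells. Cluster 3 (15 WT and 483 KO cells) had 74.2 and 56.0 CPM, and cluster 6 (75 and 294 cells) had 125 and 45.0. These clusters held more of the KO cells and had less Dab2 in WT than the class, so part of the macrophage-like ratio may go with the mix of clusters. Dab2 was lower still in KO monocyte-like cells, at 27.9 CPM (from 41 UMIs) and a log2 ratio of -1.92 (-2.42 to -1.44). It stood at 113 CPM in WT and 38 in KO in cluster 5 and at 15.6 and 2.39 in cluster 13, from 4 and 1 UMIs. Cluster 13 made up more of the KO class, so part of the class ratio goes with this mix. In KO cDC2-like cells it had 68.0 CPM (52.6 to 86.5), a log2 ratio of -1.33 (-1.73 to -0.95). KO neutrophil-like cells had 12.2 CPM from 5 UMIs. In cDC1-like cells the ratio of -1.75 had an interval from -4.30 to 0.31, so a difference was not detectable at this depth. The library preparation counts 3′ tags, which may lie outside the deleted part of the gene, so a remaining count does not measure how many cells were deleted.

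**Figure D1:**
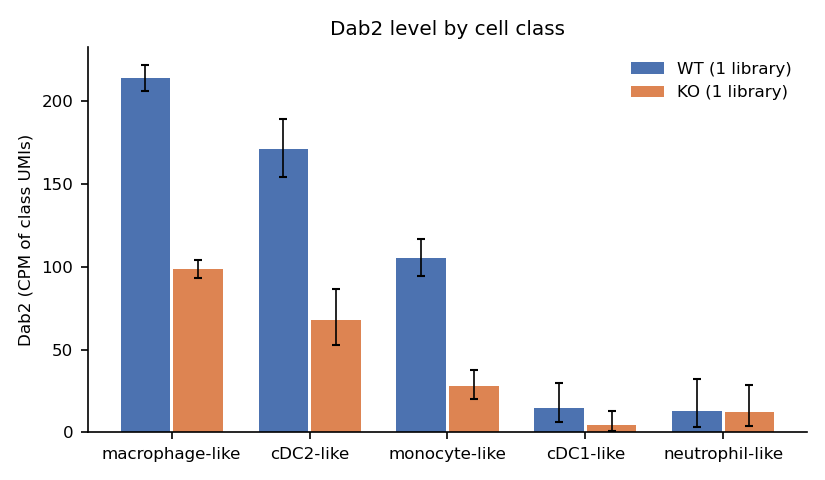
Dab2 level in CPM of class UMIs (vertical axis) for 5 cell classes (horizontal axis), 1 bar per library, with exact Poisson 95% intervals. Macrophage-like cells were highest in both libraries, at 214 CPM in WT and 98.6 in KO.

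Shares of cells with a Dab2 UMI were read after each cell was thinned to 2000 UMIs. Among macrophage-like cells the share was 32.9% in WT (30.7 to 35.1; exact binomial intervals) and 14.9% in KO (13.3 to 16.6). Among cDC2-like cells it was 23.6% and 13%, and among monocyte-like cells 12.5% and 2.71%. Neutrophil-like cells, taken as the class that should lack Dab2, gave 2.56% in WT (0.312 to 8.96) and 3.60% in KO (0.990 to 8.97). At this depth the KO monocyte-like share was not above the neutrophil-like one, so these shares alone do not separate it from background. Its level of 27.9 CPM lay above the 6.42 CPM (2.77 to 12.7) of KO neutrophil-like, cDC1-like, mature dendritic and plasmacytoid cells pooled. These classes were picked for their little Dab2 after the results were seen. The interval of KO neutrophil-like cells alone, 3.97 to 28.5 CPM, includes 27.9, so background was not excluded for KO monocyte-like cells. No UMI was found in 50 thinned KO cDC1-like cells (interval up to 7.11%), of which 6% had one without thinning, and the thinned WT share was 2.5%. Without thinning, the WT and KO shares were 64.7% and 40.6% in macrophage-like cells, 58.7% and 31% in cDC2-like cells, 29% and 7.92% in monocyte-like cells, and 1.67% and 3.18% in neutrophil-like cells. Median depths in WT and KO were 6657 and 6661 UMIs for macrophage-like cells but 2323 and 2356 for neutrophil-like cells. Thinning left out 38 WT and 33 KO macrophage-like cells, 7 and 19 monocyte-like cells, 42 and 46 neutrophil-like cells, and 2 WT cDC2-like cells.

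Macrophage-like cells made up most of both libraries, and their share was higher in KO, while monocyte-like and cDC2-like shares were lower. Macrophage-like cells were 69.6% of WT cells (67.8 to 71.3) and 76.9% of KO cells (75.2 to 78.6), a difference of 7.34 percentage points. Monocyte-like cells were 15.1% of WT (13.7 to 16.5) and 9.70% of KO (8.56 to 10.9). For cDC2-like cells the shares were 8.22% (7.20 to 9.33) and 4.04% (3.30 to 4.89). Neutrophil-like cells had shares of 4.52% (3.76 to 5.38) and 6.35% (5.42 to 7.38). The cDC1-like shares of 1.51% and 2.02%, the mature dendritic shares of 0.867% and 0.728% and the plasmacytoid shares of 0.226% and 0.243% had overlapping intervals. With each library clustered alone, the differences were 3.02 points for macrophage-like and -0.394 points for cDC2-like cells. All shares follow the sort and the loading of 1 pool of 3 mice per library.

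The main question was how macrophage-like cells of the KO library, in which part of the Dab2 transcript remained, differed in expression. In this comparison interferon-response genes were higher in KO macrophage-like cells, and immediate-early, heat-shock, alternative-activation and scavenger-receptor genes were lower. Among single genes, the Ly49-family receptor Klra17 stood highest in KO, and Chil3, Fn1 and Klf4 were among the lowest. Most genes were close to equal. Of 9180 genes with at least 100 UMIs, 93.3% lay within 1.5-fold, and the median log2 ratio was -0.04 with a central 95% from -0.71 to 0.61. The class totals were 13927574 UMIs in WT and 14031463 in KO. Most WT macrophage-like cells lay in clusters 1 and 4, and most KO ones in clusters 3, 2 and 6. Cluster 1 had 92.0% WT cells, cluster 12 had 92.6% WT cells and cluster 3 had 97.0% KO cells, and such clusters may each be a library and not a cell type.

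Klra17, which encodes a lectin-like receptor of that family, had 2.08 CPM in WT and 83.3 in KO (29 and 1169 UMIs), a log2 ratio of 5.32 (4.79 to 5.91). It was also a leading gene of cluster 3. In monocyte-like cells Klra17 was also higher in KO, with 3 and 11 UMIs (3.01; 1.09 to 5.49). Its ratio was 0.04 in both cDC2-like and neutrophil-like cells. Cd300e, an activating receptor typical of Ly6c-low monocytes, had a log2 ratio of 4.26 (3.24 to 5.49), and 2.22 in monocyte-like cells. Xcr1, the chemokine receptor of cDC1, had 13 UMIs in WT and 129 in KO (3.30), and Clec9a, a cDC1 receptor for dead cells, had 25 and 83 (1.72). In cDC1-like cells themselves Xcr1 stood at 317 CPM in WT and 357 in KO. Clec4a1, a C-type lectin of myeloid cells, had 22.0 CPM in WT and 70.9 in KO (1.69), against a log2 ratio of 0.21 in monocyte-like cells. Kctd14 (1.94), a little-studied gene, Pydc3 (1.88), an interferon-inducible pyrin-domain gene, and G0s2 (1.79), an inhibitor of fat breakdown abundant in neutrophils, were also higher in KO. For G0s2, 36.1% of the KO UMIs lay in 5 cells, and the mean of per-cell CPM gave 0.77. G0s2 was higher in KO in other classes too, with log2 ratios of 2.499 in monocyte-like and 1.73 in neutrophil-like cells. In cDC2-like cells the ratio was 3.63 (2 and 11 UMIs), and cDC1-like cells had no UMI in WT and 16 in KO. The G0s2 difference was therefore not particular to macrophage-like cells. Its KO level was 14.4 CPM in macrophage-like and 6153 in neutrophil-like cells. Without the clusters with over 80% of cells from 1 library, a setting chosen after the data were seen, Clec4a1 had 0.75, Kctd14 1.04, Xcr1 2.5 and Gzmb -3.15. Together with monocyte-like cells, Cd300e had 2.60 and Clec4a1 0.65.

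The secretoglobins Scgb2b27 (3.18; 2.65 to 3.76) and Scgb1b27 (2.30; 1.59 to 3.07), secreted proteins of glands, completed the 10 highest genes. Scgb2b27 was higher in KO in other classes too, with log2 ratios of 4.14 in monocyte-like, 5.63 in cDC2-like and 3.63 in neutrophil-like cells. Its KO level was 20.9 CPM in macrophage-like, 21.8 in monocyte-like, 22.7 in cDC2-like and 39.1 in neutrophil-like cells. Of the 31-base words in the last 500 bases of its transcripts, 12.0% were shared with other genes.

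At the low end, Chil3, a chitinase-like protein of alternatively activated macrophages and monocytes, had 24.8 CPM in WT and 4.20 in KO, a log2 ratio of -2.56 (-2.99 to -2.16). Chil3 was also lower in monocyte-like (-1.84), cDC2-like (-1.69) and neutrophil-like cells (-3.69), but higher in KO cDC1-like cells (3.83; 7 and 126 UMIs). It shares 24.5% of its 3′ words with other genes, mainly Chil4. Fn1, the matrix protein fibronectin, had 47.5 CPM in WT and 9.34 in KO (-2.35; -2.63 to -2.08), and its ratio was -0.81 in monocyte-like cells. The Fn1 ratio ran from -3.08 in cells with few immediate-early and heat-shock UMIs to -1.63 with doublet calls kept. Klf4, a transcription factor of monocytes and of stress responses, stood at 196 CPM in WT and 55.1 in KO (-1.83; -1.95 to -1.71). In monocyte-like cells the Klf4 ratio was -0.35, and in macrophage-like cells with few immediate-early and heat-shock UMIs, of which Klf4 is a part, it was -0.86. Fam71a had 40.0 and 9.34 CPM (-2.10), and Ahnak, a large scaffold protein at the membrane, 25.4 and 7.06 (-1.85, and -3.34 with each library clustered alone). Ahnak is among the leading genes of cluster 10 (151 WT and 69 KO cells) and Klf4 among those of cluster 1 (732 and 64). The mix of clusters may therefore enter these 2 ratios.

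Rab4a, a small GTPase of the recycling endosome, had 91 UMIs in WT and 14 in KO, a log2 ratio of -2.71 (-3.64 to -1.89) that was -1.70 after thinning. Gzmb, a granule protease of cytotoxic cells, had 91 and 16 (-2.52). Dusp18 (-2.17), a phosphatase, and Adgrl3 (-2.16), an adhesion receptor, were lower in KO as well. In cells with few immediate-early and heat-shock UMIs, the ratios were -1.14 for Dusp18, 1.01 for Clec4a1, 1.23 for Kctd14 and 3.17 for Clec9a. Cma1, a mast-cell chymase, had 105 UMIs in WT and none in KO. That is 35.3-fold lower with the KO count set at the floor of 3, and the exact interval ends at a log2 ratio of -4.82. Of the Cma1 UMIs, 99 came from 1 WT cell.

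**Figure D2:**
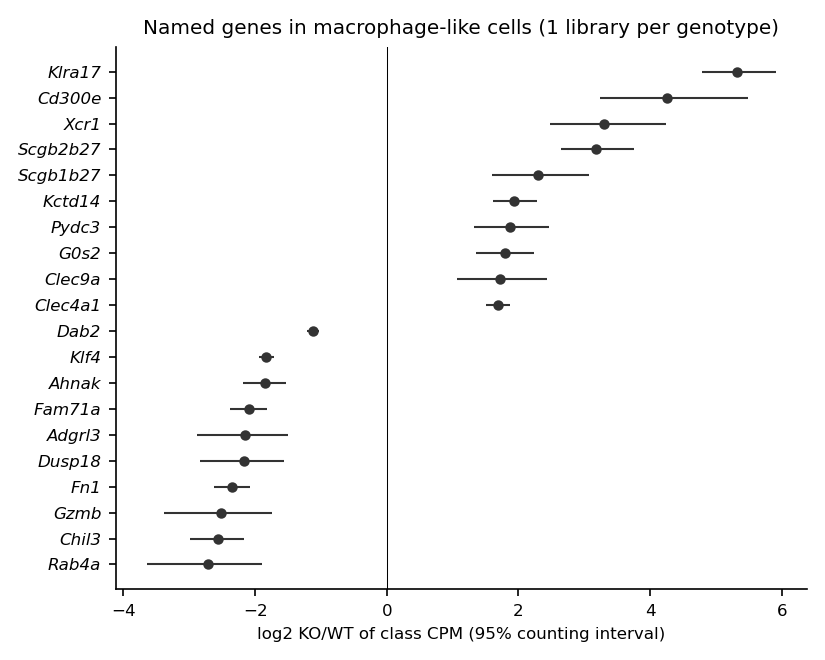
Log2 KO/WT ratio of class CPM (horizontal axis) for the named genes in macrophage-like cells, points with exact 95% counting intervals; Cma1, with no KO UMI, is not drawn. Klra17 lay highest at 5.32 and Rab4a lowest at -2.71, with Dab2 at -1.12.

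Among fixed lists, interferon-response genes stood furthest above 0 in KO macrophage-like cells. Their median log2 ratio was 0.85 (0.79 to 0.95), above all 10000 random lists matched on expression (percentile 100), and 24 of 25 genes were higher. These percentiles are a description of these libraries. Irf7, the transcription factor that amplifies type I interferon, had 80.3 CPM in WT and 205 in KO (1.35), and Ifi44 11.8 and 31.9 (1.44). Ifi204, a sensor of cytosolic DNA, had 151 and 245 CPM (0.70), and Bst2, an antiviral membrane protein, 644 and 902 (0.49). Interferon genes lead cluster 6, which had 79.7% KO cells, and without that cluster the median was 0.44. Inside single macrophage-like clusters the list was not read as a direction. Cluster 6 (median -0.43) is itself led by interferon genes, cluster 3 (-0.64) held 15 WT cells and cluster 12 (0.92) held 15 KO cells. Cluster 1 had a median of -0.09 but a summed level of 1491 CPM in WT and 1637 in KO. In the other 6 clusters the median was higher in KO, from 0.16 in cluster 11 (6 list members) to 1.40 in cluster 14. Genes of antigen presentation on MHC class I were also higher, with a median of 0.22 (percentile 100; 12 of 16 genes). B2m, the light chain of class I molecules, had 5484 and 7557 CPM (0.46), and H2-Q7 had 69.3 and 106 (0.62). The ratios of H2-Q6 and H2-D1 were 0.58 and 0.15.

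Immediate-early and heat-shock genes, which also respond to tissue digestion, had the lowest median, -0.76 (-0.78 to -0.73, percentile 0), and 22 of 23 genes were lower in KO. Dusp1, an early-response phosphatase, had 1441 CPM in WT and 577 in KO (-1.32). The chaperones Hspa1a (-0.76) and Hspa8 (-0.69) were lower as well, at 3288 and 1946 CPM for Hspa1a. The median was -0.35 without the clusters with over 80% of cells from 1 library. Over 14 settings it ran from -0.77 to -0.21, at percentile 0 in each. Per 2000 UMIs of a macrophage-like cell, the median was 58 UMIs of this list in WT and 30.5 in KO.

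Alternative-activation genes had a median of -0.41 and a mean of -0.58 (percentile 0; 14 of 17 lower). Arg1, the arginase of alternatively activated macrophages, was low in both libraries, at 6.75 CPM in WT and 2.78 in KO (-1.28; -1.86 to -0.73), and its list also held Chil3, Il4ra (-0.37) and Sepp1 (-0.13). The list median lay further from 0 in several settings, at -0.93 with each library clustered alone and -0.69 at resolution 0.5. Scavenger and lipoprotein receptors, several of them cargo receptors for endocytosis, had a median of -0.36 (percentile 0; 11 of 14 lower). Cd36, a receptor for fatty acids and oxidised lipoprotein, had 52.8 and 21.1 CPM (-1.32), and Lrp12 had a ratio of -0.78, against -0.15 for Axl and 0.10 for Cxcl16. Genes of lipid handling had a median of -0.24 (percentile 0.06; 12 of 18 lower). Lpl, lipoprotein lipase, was at 134 CPM in KO (-1.11), whereas Apoe had -0.15 and Lgals3 0.03; with monocyte-like cells added, the list median was -0.11. Cholesterol-synthesis genes had a median of -0.20 (percentile 2.43), a place that did not hold: over 14 settings the median ran from -0.43 to -0.025 and the percentile from 0 to 46. Members ranged widely, with Cyp51 at -0.54, Hmgcr at -0.42, Msmo1 at -0.08 and Fdps at 0.24.

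Integrin and focal-adhesion genes had a median of -0.25 (percentile 0.01; 18 of 21 lower). Cd44, a receptor for hyaluronan, had 96.8 and 53.0 CPM (-0.87), the integrin chains Itgb7 and Itgb5 had -0.87 and -0.20, and the actin regulator Vasp had 0.05 (-0.01 to 0.12). Endocytic adaptors and clathrin, the group that Dab2 works with, had a median of -0.12 (percentile 5.48), with Hip1 at -0.74, Rab4a at -2.71, the clathrin light chain Clta at -0.02 and Arrb2 at -0.09. Matrix-remodelling genes had a median of -0.06 (percentile 29.3) but a mean of -0.31. Mmp12, the macrophage elastase, had 633 CPM in WT and 210.2 in KO (-1.59), and it leads clusters 1, 8 and 12. The matrix median was -0.23 in cells with few immediate-early and heat-shock UMIs and -0.19 with members of at least 10 UMIs, both below the random lists. Ctsb (-0.06) and Ctss (0.16) moved little.

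Inflammatory-activation genes had a median of -0.36 (percentile 0; 13 of 18 lower), and chemokines and cytokines one of -0.23 (percentile 0.03; 18 of 28 lower). Cxcl2, which attracts neutrophils, had 2453 and 823 CPM (-1.58), and Ccl4 3611 and 2492 (-0.53). Ccl5, a chemokine for T cells, went the other way, with 171 CPM in WT and 425 in KO (1.31), as did the growth factor Vegfa with 7.75 and 22.5 (1.53). Vegfa leads cluster 8 (79 WT and 205 KO cells), at 101 CPM against 6.05 in the other macrophage-like cells. Ccl5 is among the leading genes of cluster 3 (15 WT and 483 KO cells). The inflammatory and chemokine medians turned, to 0.11 and 0.12, without the clusters with over 80% of cells from 1 library. In cells with few immediate-early and heat-shock UMIs the chemokine median was 0.04. This pair of settings was chosen after the data were seen. Oxidative-phosphorylation genes had a median of 0.10 (percentile 98.7) and proliferation genes 0.08 (percentile 97.9), and both medians turned in that pair of settings. They were -0.05 and -0.06 for oxidative phosphorylation and -0.17 and -0.26 for proliferation. Together with monocyte-like cells, the oxidative-phosphorylation median was -0.02. The places of these 2 lists above the random lists were also lost under some of the cell filters and resolutions. Cox8a (0.25), Cenpf (0.60) and Ube2c (0.59) were higher, and Uqcrc1 (-0.25) and Hmgb2 (-0.31) lower.

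The other 7 lists lay within the central 95% of random lists in the main setting. The medians were -0.11 for MHC class II genes, -0.03 for the lysosome, 0.02 for the TGF-beta response, -0.01 for YAP and TAZ targets (mean 0.06), 0.04 for hypoxia and glycolysis, -0.04 for complement and Fc receptors, and -0.04 for immune checkpoints. Medians this near 0 carry no firm direction: the lysosome median was 0.01 and that of YAP and TAZ targets 0.03 when scaled by the median ratio, and the checkpoint median was 0.01 without the clusters with over 80% of cells from 1 library. In cells with few immediate-early and heat-shock UMIs, the hypoxia median was -0.31 (percentile 0). The TGF-beta median was 0.10 (percentile 99.3) without those clusters. Single members still differed. Cd80, a T-cell co-stimulator, was lower (-0.98) while Cd74 (-0.07) and H2-Ab1 (-0.02) were close to equal. Smad6 was higher (1.42) and Id1 lower (-0.77), Cfb was higher (1.06) and Cfh lower (-0.86), and Cd274, which encodes PD-L1, had 6.39 and 13.2 CPM (1.04).

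Lists shared members: Cd36 counted for scavenger receptors and lipid handling, Axl for scavenger receptors and YAP and TAZ targets, Cxcl16 for scavenger receptors and chemokines, and Arg1 for alternative activation and checkpoints. Cxcl2, Ccl4 and Ccl5 counted for inflammatory activation and chemokines, Vegfa for chemokines and hypoxia, and Ctss for matrix, MHC class II and the lysosome. As fixed, the scavenger-receptor and alternative-activation lists shared Mrc1 and Cd163, so their medians are not fully separate observations. The integrin and complement lists shared Itgam and Itgb2, and the matrix and lysosome lists Ctsb, Ctsd and Ctsl. Further members were shared as well.

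**Figure D3:**
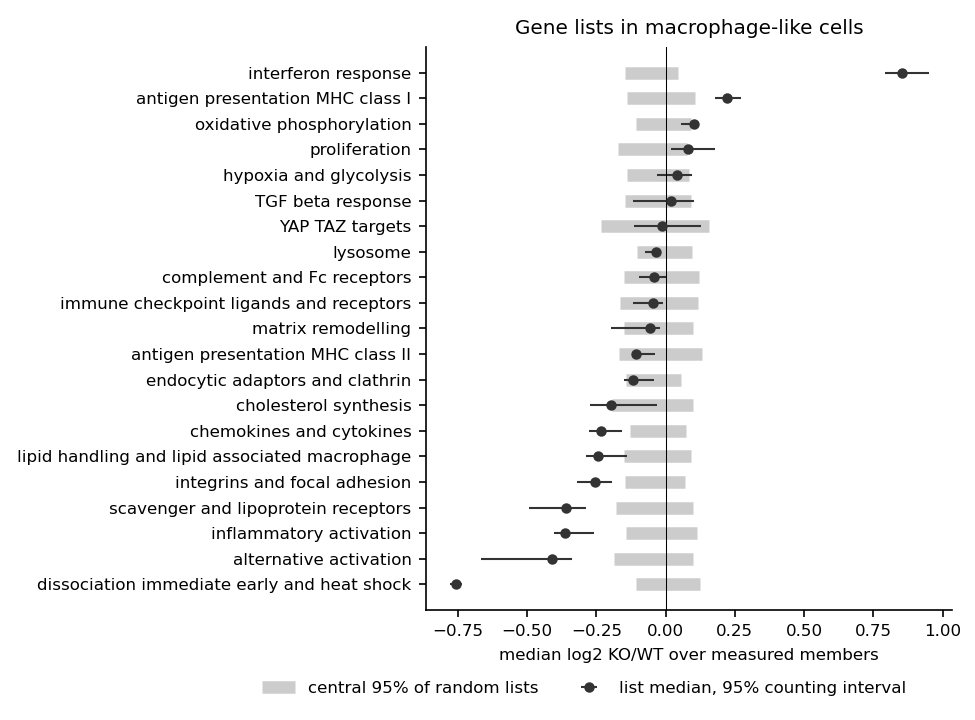
Median log2 KO/WT ratio (horizontal axis) of 21 gene lists in macrophage-like cells, points with 95% counting intervals, over grey bars for the central 95% of 10000 matched random lists. Interferon-response genes lay highest at 0.85 and immediate-early and heat-shock genes lowest at -0.76; the lysosome median turned to 0.01 when scaled by the median ratio.

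Marker genes of other cell types were summed in macrophage-like cells as a measured fact beside these groups. Several sums rested on 1 or 2 genes, which were left out in turn after the values were seen. Neutrophil markers had a log2 ratio of -1.17 through Cxcl2 alone: without it they were higher in KO (0.92), and 11 of 13 were higher, among them S100a8 (1.45) and S100a9 (1.65). Epithelial markers had 0.61, but -0.37 without Wfdc18 and Csn3, and Epcam (-0.60), Krt8 (-0.51) and Krt19 (-0.70) were lower. B-cell and plasma-cell markers had 0.92, and -0.01 without Cd79b. Mature dendritic markers had 0.91, and -0.11 without Ccl5. Plasmacytoid markers had 0.37, and -0.11 without Bst2. Endothelial markers had 0.74, and 0.29 (-0.24 to 0.83) without Kdr.

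Macrophage markers had -0.05, and 0.10 without Apoe. Monocyte markers had -0.04, and -0.62 without Ms4a4c. The cDC1 markers had -0.05, 0.00 without Irf8, and 0.10 (0.04 to 0.16) without Irf8 and Naaa. Of 11 cDC1 markers, 9 were higher in KO and 2 lower, with Xcr1 (3.30) and Clec9a (1.72) among the higher ones. For cDC2 markers the ratio was -0.24, and -0.04 (-0.10 to 0.03) without Tnip3 and Mgl2. T-cell markers (-0.87), NK and innate lymphoid markers (-0.65), mast-cell and basophil markers (-3.86, and -2.99 without Cma1) and erythroid markers (-1.17) were lower with and without their leading gene. Eosinophil markers had -0.77, and -0.51 (-1.19 to 0.16) without Ear2. Fibroblast markers had -0.55 (-1.24 to 0.12).

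The next question was whether the same genes differed in the other myeloid classes. Immediate-early and heat-shock genes were lower in all 4 classes compared. Interferon-response genes were not higher in all: their medians were -0.32 in monocyte-like, -0.27 in cDC2-like and 0.24 in neutrophil-like cells. Without the 5 cells of each library with most of the list's UMIs, a setting chosen after the data were seen, they were -0.31, 0.12 and 0.53. These classes held far fewer cells, so single cells weighed more.

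In monocyte-like cells, MHC class II, matrix and lysosome genes were lower in KO. Macrophage markers were lower with them (-0.52), all 12 of them, with C1qa at -0.85, C1qb at -0.86, Mafb at -0.77 and Pf4 at -1.99, so these lists were not separated from a lower macrophage signal in the class. The cDC2 markers (-0.48) and T-cell markers (-1.01) were lower in these cells as well, so a lower content of other cells is not narrowed to macrophages. MHC class II genes had a median of -0.46 (percentile 0.03), with Cd74 at -0.62 and H2-Ab1 at -0.58, whereas MHC class I genes had 0.05 (percentile 80.9). Matrix remodelling had a median of -0.47 and a mean of -1.08, with Timp1, an inhibitor of metalloproteinases, at 98 UMIs in WT and 1 in KO. Mmp12 had 247 and 7 UMIs (-4.00), and Adam8, a membrane protease, had a ratio of -2.59. Alternative-activation genes had -0.63, scavenger receptors -0.41, chemokines -0.38, complement and Fc receptors -0.33, checkpoints -0.28, the lysosome and hypoxia lists -0.26, and inflammatory activation -0.22. Arg1 (-2.07) had 73.9% of its WT UMIs in 5 cells. Immediate-early and heat-shock genes had -0.34 (percentile 0.01), with Fos at -0.46 and Atf3 at -0.76. The interferon list (-0.32; -0.49 to -0.16; 21 of 23 lower) was at -0.14 in the Ly6c2-high cluster alone, a setting chosen after the data were seen. There MHC class II genes had -0.29, alternative activation -0.28, matrix remodelling -0.26, chemokines -0.25 and checkpoints -0.14. The interferon, alternative-activation and checkpoint medians then lay within the random lists.

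Higher in KO monocyte-like cells were Fabp4, a fatty-acid carrier that leads cluster 13 (14.8 and 115 CPM; 2.95), Cd300e (2.22), the lincRNA Mir142hg (1.77) and Ly6i (1.75). Ccl5 was higher too (1.91), but 81.0% of its KO UMIs lay in 5 cells. Rgcc (-2.28) and Dmkn (-2.12) were lower. Cluster 5, led by Chil3 and Ly6c2, had 343 WT and 138 KO cells and cluster 13 had 57 and 102, so the mix of monocytes differed between libraries.

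In cDC2-like cells, inflammatory, chemokine and complement genes were lower in KO, and proliferation genes higher. Macrophage markers were lower in the same cells (-0.46, all 12), with C1qb at -0.40, C1qc at -0.51, Apoe at -0.56 and Trem2 at -0.89, and C1qa, C1qb and C1qc are also members of the complement list. T-cell markers had -0.97, and neutrophil markers -0.56 but 0.26 without Cxcl2. Inflammatory activation had a median of -0.50 and a mean of -0.84 (percentile 0; 14 of 15 lower). Cxcl9, an interferon-gamma-induced chemokine, had 62 UMIs in WT and 1 in KO, and Cxcl10 had a ratio of -1.58. Chemokines had a median of -0.41, complement and Fc receptors -0.45 with Fcgr1 at -0.96, hypoxia -0.37, integrins -0.29, matrix -0.23 and the TGF-beta response -0.23. Immediate-early and heat-shock genes had -0.49 (percentile 0), with Dusp1 at -0.92 and Klf2 at -0.91. Proliferation genes had 0.36 (9 of 10 higher). The interferon median of -0.27 turned to 0.12 without the 5 cells of each library that held most of the list's UMIs, so it rests on a few cells.

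Of the genes named in cDC2-like cells, S100a9 (1.51), Tnrc6c (1.48), H2afx (1.10) and Wfdc18 (1.09) were higher in KO. Ccl24 (4.93) had 172 of its 176 KO UMIs in 1 cell. Hmox1 (-2.27), Ccl17 (-2.15), Lyz1 (-2.04), Ifi205 (-1.88) and Rsad2 (-1.82) were lower, and each had over 50% of its WT UMIs in 5 cells.

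In neutrophil-like cells, immediate-early and heat-shock genes were lower in KO (-0.62, percentile 0), with Jun at -1.34 and Hsp90ab1 at -1.45, although Dusp1 was higher (0.33). Erythroid markers were higher in the same cells (2.18; 1.65 to 2.75, and 1.90 without Hba-a1), as were neutrophil markers (0.44), and T-cell markers were lower (-1.32). Hypoxia and glycolysis genes were lower as well (-0.43, percentile 0.31). The interferon median of 0.24 (percentile 98.5; 9 of 11 higher) had an interval from -0.02 to 0.53, with Isg15 at 0.73 and Bst2 at -1.17. G0s2 had 1860 CPM in WT and 6153 in KO (1.73). Rgs1 (-1.81) and Xbp1 (-1.72) were lower. The other extreme genes came from few cells: Ctla2a (6 UMIs in WT and 249 in KO), Prok2 (2.09), Saa3 (1.99), Camp (-3.61), Ltf (-3.34) and Ngp (-1.68) each had over 80% of the UMIs of the higher library in 5 cells, and Ppbp had 100 UMIs in 1 KO cell. Scaling by the median ratio removes a class median of -0.11 in log2, which raises each ratio of this class by that size.

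**Figure D4:**
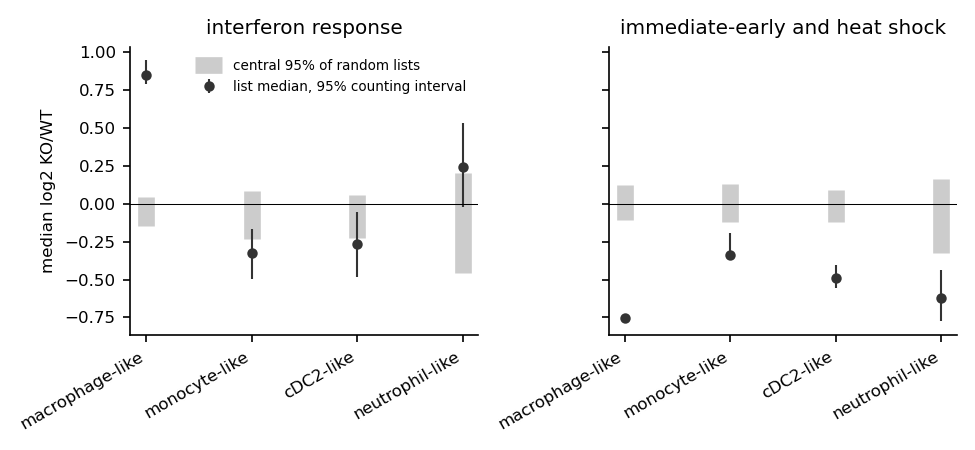
Median log2 KO/WT ratio (vertical axis) of interferon-response and of immediate-early and heat-shock genes in 4 cell classes, points with 95% counting intervals, over grey bars for the central 95% of matched random lists. The interferon median was 0.85 in macrophage-like and -0.32 in monocyte-like cells, and the cDC2-like one turned to 0.12 without 5 cells per library; the other list was lower in KO in all 4 classes.

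The last question was which genes went with Dab2 among WT macrophage-like cells, with KO cells read beside them. After thinning, 594 WT cells had a Dab2 UMI and 1214 had none; in KO the numbers were 279 and 1591. WT cells with Dab2 had more alternative-activation transcript (median log2 ratio 0.32, percentile 99.9, with 6 of 10 members higher and 4 lower), more lipid-handling transcript (0.18) and more lysosome transcript (0.09). The same lists were higher in KO cells with Dab2, at 1.15, 0.27 and 0.07. Complement and Fc receptors had 0.09 in WT (percentile 98.4, but 75.8 without thinning) and -0.06 in KO. Interferon-response genes were lower in cells with Dab2, at -0.12 in WT (percentile 1.07) and -0.40 in KO (percentile 0), as were MHC class I genes, at -0.08 and -0.22. Inflammatory activation (-0.16), immediate-early and heat-shock genes (-0.08) and proliferation (-0.19) were also lower in WT cells with Dab2, against 0.02, 0.05 and -0.15 in KO. Proliferation lay within the random lists without thinning (-0.028, percentile 12.3) and with at least 2 Dab2 UMIs required (-0.17, percentile 11.5). With that stricter split, the WT medians for alternative activation, lipid handling and immediate-early and heat-shock genes were 0.64, 0.44 and -0.30. Lists inside the random range in the main setting left it both without thinning and with that split: hypoxia (0.41 and 0.32), matrix (0.22 and 0.23) and MHC class II (-0.15 and -0.20).

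Ccl8, a chemokine of resident-type macrophages, had a log2 ratio of 1.23 in WT cells (0.87 to 1.60) and of 2.46 in KO cells (2.07 to 2.85). It was the 1 gene of the 10 highest whose KO interval lay above 0. The other genes highest in WT cells with Dab2 were Ifitm1 (1.68), an antiviral membrane protein, Rnasel (1.48), Fam98b (1.46), Atr (1.35), Acsl4 (1.28), Wrap73 (1.26), Npl (1.18), Ugcg (1.16) and Agtrap (1.13). The 10 lowest ran from Snhg9 (-1.64) and Pik3r2 (-1.62) to Hmgcs1 (-1.11), and each of their KO intervals included 0. These values describe cells within a library, and few UMIs lay behind the single genes.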

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

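The tests of passenger regions, of free Dab2 RNA over 4 classes together, of a like loss in every cell and without the 5 cells with most interferon UMIs were chosen only after the results were seen. The interferon list stood out because its median log2 KO/WT ratio was positive in macrophage-like cells, 0.85 (0.79 to 0.95), and negative in monocyte-like cells, -0.32 (-0.49 to -0.16), and cDC2-like cells, -0.27 (-0.48 to -0.06). The difference between classes was not tested. The cDC2-like median turned to 0.12 without 5 cells per library, and the monocyte-like one was -0.14 in the Ly6c2-high cluster alone.

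Free RNA in the KO droplets would raise the interferon list in every class. The difference in its summed CPM, KO minus WT, was 1085 in macrophage-like cells, but -286 in cDC2-like cells (upper bound -189; -45.3 without 5 cells per library) and -213 in monocyte-like cells (upper bound -130.2). That argues against free RNA as the whole source. Neutrophil-like cells had a gain of 867 (614 to 1121), or 966 without 5 cells, and a part from free RNA was not excluded. A stronger handling response in WT cells could lower these genes, but in cells with a low handling response the median was 0.67 (0.63 to 0.85), above 0.43, which is 0.5 times the main median. Without cluster 6 the list was still higher in KO, with a median of 0.44 (0.38 to 0.53). That argues against a larger share of this cluster as the whole source. The interval spans that same 0.43, so the parts from the share and from a change in each cell cannot be told apart. The mice, pool and sort also stay open.

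Dab2 was still counted in KO macrophage-like cells, at 98.6 CPM. KO neutrophil-like cells had 12.2 CPM, whose interval of 3.97 to 28.5 alone left free RNA open. The 4 classes with little Dab2, picked for that, together had 6.42 (2.77 to 12.7), under the bound of 23.4. Depth differs, with medians of 13296 UMIs in KO cDC1-like and 6661 in KO macrophage-like cells. By cells, 50 KO cDC1-like cells held 3 Dab2 UMIs and 157 neutrophil-like cells 5, against 1384 in 1903 macrophage-like cells. That argues against free RNA as the whole source, and a part from it was not excluded. Of thinned KO cells, 3.21% (2.46 to 4.11) had at least 2 Dab2 UMIs. A minority of cells that kept the whole transcript would need 3.87%, which lies inside that interval. A like loss in every cell would give 2.15%. Both shares assume the WT mix of clusters, which differed in KO, where Dab2 ran from 45.0 CPM in cluster 6 to 280.5 in cluster 12. The comparison therefore cannot decide between a minority and a like loss. A shortened transcript that keeps its 3′ end may also contribute, and the 1384 UMIs cannot decide it because counts per exon were not used here. The minority, a like loss in every cell and the shortened transcript all stay open.

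The 10 highest and 10 lowest genes in macrophage-like cells do not come from a few cells as sets: the median share of UMIs in 5 cells was 9.79% and 10.8%, although Cma1 had 98.1%. A difference in genetic background between the pools that acts in every class may hold for some of them. In other classes, the median was 0.96 over 8 of the highest genes (0.81 to 2.62, with 1.06 needed) and -0.53 over 9 of the lowest (-2.19 to 0.00, with -1.13 needed). Both intervals come from redrawing the genes, so they show the spread between genes and hold no counting error. Dab2 itself was lower in KO monocyte-like (-1.92) and cDC2-like cells (-1.33), so an effect of genotype could appear there as well. A ratio shared by monocyte-like or cDC2-like cells therefore cannot tell background and genotype apart. Neutrophil-like cells had little Dab2 in either library (12.7 CPM in WT and 12.2 in KO). There Scgb2b27 (3.63), G0s2 (1.73) and Chil3 (-3.69) differed in the same direction as in macrophage-like cells, while Klra17 (0.04) did not. Most of the other named genes had few UMIs in that class, so it did not settle the question for the sets. Of 32 genes with an absolute log2 ratio of at least 1.5, 10 had another within 5 Mb, against a median of 6 in 10000 random draws (percentile 91.2), which leaves passenger regions open too.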

How the results depend on the processing

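No paired analysis was possible because each genotype has 1 library of pooled mice. The alternatives on clusters mostly from 1 library, the handling response, the top 5% of doublet scores, the Ly6c2-high cluster and the 5 cells with most interferon UMIs were added after the data were seen. Of the values that answer a comparison, 118 stayed within the set limits and 20 moved; of the others, 639 stayed, 123 moved and 11 reversed. A value counts as reversed where its main 95% counting interval excludes 0 and its sign changed; a sign change from an interval that includes 0 is counted by size alone. The macrophage-like Dab2 ratio lay between -1.30 and -1.01 over 11 settings and was lower in KO in each.

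The median of the 10 lowest genes (main -2.26) was -2.04 with thinned cells, -1.99 with monocyte-like cells added, -1.77 at a minimum of 300 UMIs and -2.56 with each library clustered alone. The median of the 10 highest was 1.62 at 300 UMIs, where 4 genes were shared, and 2.87 in cells with a low handling response. Dab2 was at -1.01 without clusters over 80% from 1 library and at -1.30 in cells with a low handling response. Without thinning, the WT Dab2 share was 64.7%, and the genes that go with Dab2 had medians of 0.39 and -0.15. Deeper cells more often have a Dab2 UMI, and these genes were picked as the extremes of the thinned counts. Which of these moved the medians was not tested.

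Share differences in points were -2.78 for cDC2-like cells with no cell filter and -2.77 at resolution 0.5, where monocyte-like cells had -7.52. With each library clustered alone they were 3.02 for macrophage-like, -0.394 for cDC2-like and -0.867 for mature dendritic cells. Above the random lists lay 1 monocyte list and 2 cDC2 lists at a minimum of 10 UMIs, and 1 monocyte list in the Ly6c2-high cluster alone.

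Reversed medians were the lysosome at 0.0073 scaled by the median ratio, and oxidative phosphorylation at -0.020 with monocyte-like cells added. Without clusters over 80% from 1 library, inflammatory activation was 0.11, chemokines 0.12, oxidative phosphorylation -0.053, proliferation -0.17 and checkpoints 0.012. In cells with a low handling response, chemokines were 0.041, oxidative phosphorylation -0.058 and proliferation -0.26. The cDC2-like interferon median was 0.12 without the 5 cells with most of its UMIs. Macrophage-like medians with an interval that includes 0 also changed sign: hypoxia was -0.31 in cells with a low handling response, TGF-beta reached -0.11, YAP and TAZ targets 0.064 and complement 0.017. Cholesterol synthesis ran from -0.43 to -0.025. Apart from those 5 cells, the cause was not tested.

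Plasmacytoid cells were not found at resolution 0.5, with each library alone or without the top 5% of doublet scores. Cma1 gave no value with thinned cells, under the stricter cell filter or in cells with a low handling response, where under 10 UMIs were left. Depth left the Dab2 difference in cDC1-like cells undetectable.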

Other observations

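These 4 genes were chosen after their values were seen and belong in no comparison above. Gm8730, a processed pseudogene on chromosome 8 (102864845 to 102865798, GRCm38), had 548 UMIs in WT and 11525 in KO macrophage-like cells, a log2 KO/WT ratio of 4.38 (4.26 to 4.51). The Gm8730 ratio was 4.24 in monocyte-like, 3.80 in cDC2-like and 3.30 in neutrophil-like cells. Of its 31-base words, 67.0% were shared with Rplp0 on chromosome 5, whose ratios were -0.24, -0.18, -0.08 and -0.99 in the same classes. The Gm8730 values are therefore not read as a change in expression: a sequence variant of Rplp0 in 1 pool that moves reads between them was not tested, and falls under the background difference left open for the 10 highest genes (0.96 in other classes). Gm3336, on chromosome 8 (70718543 to 70722634), had 137 and 7 UMIs in macrophage-like cells, a ratio of -4.30. Mucl2, on chromosome 15 (103895855 to 103899312), had 91 UMIs in WT macrophage-like cells and none in KO. That is 30.6-fold lower with the KO count set at the floor of 3, and the exact interval ends at a log2 ratio of -4.61. In the other 3 classes Mucl2 had 19, 20 and 12 WT UMIs against none in KO.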
